A study of Mus musculus with 8 samples.

How the data were processed

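Striatal total RNA of 8 mice, 4 CHL2 mutants with the expanded repeat on both Htt copies and 4 wild-type mice of the same age, was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 per mouse. Per the labels' protocols the RNA was extracted with TRIzol and RNeasy columns and labelled with biotin by in vitro transcription, and the strain was C57BL/6 X CBA F1 hybrid. The deposited values are on the log2 scale, 1 per probe set and array. Per the submitters' processing notes the authors used RMA and the affy package, and versions and the set of arrays normalized together are not given in the sources used here. RMA subtracts background, forces the arrays to 1 distribution and summarises probes per probe set, so a shift shared by most genes of an array cannot be seen, and fold changes of dim genes are compressed. The log2 scale was checked from the values, which ran from 2.60 to 14.1, and the near-equal quartiles of all arrays. No value was changed before the fit, and no array was left out. The labels' mouse numbers name separate animals, and no number is shared between the groups.

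The table held 45101 probe sets, of which 64 controls were left out. Of the other 45037, 34945 had 1 gene symbol in the platform annotation used here, 932 had several and 9160 were not listed in it, and those with several or none were not named. Each gene was represented by its single-symbol probe set with the highest mean over the 8 arrays, which gave 18194 genes, 9009 of them with more than 1 probe set. Identifiers of 18032 of these genes were found in the reference gene table of the mouse, and 0 symbols changed. That table was used for names and for gene order along chromosomes alone, so no coordinates are given.

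The main test was limma's lmFit and eBayes, without trend or robust options, on the log2 values with genotype and recorded sex as terms, followed by Benjamini-Hochberg adjustment over all genes. Genes with an adjusted p under 0.05 were said to rise, fall or differ. Log2 fold changes are mutant minus wild type and adjusted for sex, so they can depart from the difference of the group means, and fold values are computed from them. Sex was a term because 3 of the 4 mutants and 1 of the 4 wild-type mice were female. The same fit gave the comparison of the sexes, and a fit with an interaction term asked whether the effect of genotype differed between them, with 1 mouse in 2 of the 4 combinations. Every Htt probe set was also tested among all non-control probe sets.

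Before the data were examined, 31 gene lists were fixed: shared, direct pathway and indirect pathway medium spiny neuron markers, striatal interneurons, G protein and cyclic nucleotide signalling, calcium signalling, potassium and sodium channels, glutamate and GABA receptors and transport, immediate early genes, neuropeptides, cholesterol synthesis, respiratory chain, heat shock and chaperones, proteasome, p53 targets, protocadherin beta genes, developmental transcription factors, interferon response, circadian clock, glucocorticoid response, astrocytes, reactive astrocytes, microglia, oligodendrocytes, their precursors, endothelial and mural cells, choroid plexus and ependyma, cortical neurons, other non-striatal neurons, blood, and sex-linked genes. Lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry, each adjusted over the 31 lists. A list's score in a mouse is the mean over its members of the log2 value minus that gene's mean over the 8 mice. Scores and RNA quality measures were compared with two-sided exact permutation tests over all 70 assignments of 8 mice to 2 groups of 4, whose smallest p is 0.0286. These tests held no term for sex. RNA quality was read from the 3' minus 5' difference of the Gapdh and beta-actin control probe sets. The share of changed genes near Htt was compared with that elsewhere by a two-sided Fisher's exact test.

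Named genes followed a rule that was fixed with the lists: Htt, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, the 3 members with the lowest adjusted p of each list with a gene past the threshold (4 for the medium spiny neuron lists), Xist and Ddx3y, the 5 genes with the lowest adjusted p between the sexes, and Gfap, Aif1, Mbp, Ppp1r1b, Drd1, Drd2, Adora2a, Penk, Tac1, Bdnf and Ppargc1a. Exceptions are named as such. Adora2a and Ddx3y had no probe set assigned to a single gene in the annotation used here.

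Alternatives planned before the data were examined were a fit without sex, a trended and robust prior, quantile normalization again, median centring, removal of the dimmer genes below the median level, the mean of a gene's probe sets, every probe set on its own, array weights, no moderation, a floor at log2 of 32, each mouse left out in turn, other list tests, other windows around Htt and other p thresholds. Fits without sex and without mice 161, 191, 170, or 161 and 170, were added after seeing the data.

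The fit was tested on simulated data, in 5 repeats of 18194 genes with 200 genes changed by known folds. Each gene had independent normal noise at its moderated residual spread. The real data gave 2258 calls and can hold correlated genes, so the shares below need not hold in them. For the comparison of mutant with wild type it recovered 8.8% of genes raised by 25% or lowered by the same factor, 85.2% of genes changed 1.5-fold, 98.8% of those changed 2-fold and 100% of those changed 3-fold, and 7.22% of its calls were genes that had not been changed. Analyses used R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.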

Results

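Gene expression was measured in the striatum of 8 mice aged 22 months, of which 4 were CHL2 mutants and 4 were wild type. CHL2 mice are a knock-in model of Huntington's disease in which a stretch of 150 CAG repeats from exon 1 of the human disease gene sits in the mouse's own Htt gene, here on both copies. The mutant group held mice 141, 153 and 154, which were female, and mouse 191, which was male. The wild-type group held mouse 161, which was female, and mice 170, 180 and 200, which were male. Each mouse gave 1 array, and the comparison of the groups asks which striatal transcripts differ in old mice that carry the expanded repeat. Medians of the arrays lay between 4.95 and 4.98 on the log2 scale. Pairs of arrays within a group correlated at r = 0.990 to 0.996 over all probe sets, and pairs between the groups at r = 0.983 to 0.991. The first principal component held 47.6% of the variance and placed the 4 mutants between -21.2 and -16.2 and the 4 wild-type mice between 15.6 and 21.0. The number of mice, 4 per group, limits the precision of every value below.

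Mutant striatum had lower levels of most transcripts typical of medium spiny neurons, the main output neurons of this tissue, and higher levels of 11 of 22 protocadherin beta genes, of 9 of 34 proteasome subunit genes, though of 1 without either of mice 161 and 191, and of single genes such as Shox2. Of 18194 genes tested, 2258 (12.4%) differed between the genotypes at an adjusted p under 0.05. Of these, 1164 (6.40% of genes tested) were higher and 1094 (6.01%) lower in the mutants. Larger changes leaned towards falls. Among the 758 genes that differed at least 1.5-fold, 290 were higher and 468 lower, and among the 170 that differed at least 2-fold, 50 were higher and 120 lower. The 8 values did not overlap between the groups for 1964 of the 2258 genes, and for 3760 of all genes tested, where chance gives 2.86% of genes. Without mutant 191, 702 genes passed, and without wild-type 161, 864 passed. Each of these mice is the single animal of its sex in its group. With sex in the fit, leaving out 191 compares the female mutants with wild-type 161 alone. Leaving out 161 compares mutant 191 alone with the male wild-type mice. For every gene the main log2 change is the mean of the log2 changes of these fits. Mice 161 and 191 therefore weigh more in it than any other mouse. With sex left out of the fit as well, 2497 genes passed without 191 and 2400 without 161.

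Htt, the gene that carries the expanded repeat, was itself lower in the mutants. Its brightest probe set fell by 0.67 on the log2 scale (SE 0.09, adjusted p = 0.00101), from 7.86 ± 0.07 (SD, n = 4) in wild-type to 7.28 ± 0.16 in mutant mice, and the values of the groups did not overlap. Tested as separate probe sets, the other 3 for Htt gave log2 changes of -0.56 (adjusted p = 0.0701), -0.49 (adjusted p = 0.00917) and -0.65 (adjusted p = 0.00773). All 8 values of the probe set at -0.49 lay under 5, the log2 of the floor of 32 used as an alternative, so that value rests on signal near background. Where these probe sets lie relative to the replaced part of exon 1 was not analysed here, so Htt does not check the genotype labels.

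The largest measured rise was in Shox2, a homeobox transcription factor of limb and heart development, from 3.76 ± 0.14 (SD, n = 4) in wild-type to 8.08 ± 0.36 in mutant mice, a sex-adjusted rise of 18.9-fold (log2 change 4.24, SE 0.17, adjusted p = 7.83e-07). Sfmbt2, a polycomb group gene, rose 5.81-fold and Skor1, a transcriptional corepressor, 5.62-fold. The transcript C130021I20Rik rose 5.33-fold and the protocadherin Pcdh20 4.67-fold. Cast, which encodes the calpain inhibitor calpastatin, rose 3.68-fold, Kazald1 3.39-fold, AW551984 3.32-fold and Zfhx2os 2.98-fold, and the neuropeptide gene Spx rose by 1.58 on the log2 scale. Adjusted p for these 10 genes lay between 6.44e-07 and 0.000235, and the values of the groups did not overlap for any of them. For 8 of the 10, all but Cast and Kazald1, all wild-type values lay under 5, so their exact folds rest on signal near background. With values held at that floor Shox2 still ranked first among the rises, at 8.01-fold, while the other 7 stood between 2.15-fold for Zfhx2os and 3.72-fold for Skor1. Of 3 probe sets for AW551984, 1 lay in the opposite direction.

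By measured value Abi3bp fell furthest, an extracellular matrix protein gene, from 7.01 ± 0.14 (SD, n = 4) in wild-type to 3.50 ± 0.23 in mutant mice, 10.9-fold lower (adjusted p = 6.44e-07). Ryr1, a calcium release channel of internal stores, was 7.53-fold lower and the glutathione peroxidase Gpx6 7.46-fold lower. Scn4b, a sodium channel beta subunit abundant in striatum, fell by 2.49 on the log2 scale (SE 0.09) from 12.42 ± 0.21, 5.63-fold lower. Ddit4l was 5.14-fold lower, Rspo1, a secreted activator of Wnt signalling, 4.17-fold, the carbonic anhydrase Car12 4.03-fold, the cyclic AMP-regulated phosphoprotein Arpp19 3.88-fold and Lrrc10b 3.74-fold. Egr2, an immediate early transcription factor, also stood among the 10 largest falls (log2 change -2.31, SE 0.55, adjusted p = 0.0207), with an SD of 1.51 in the wild-type group. Its call was lost without wild-type 161 (log2 change -0.88, adjusted p = 0.391), its change was -3.73 without mutant 191, and the call was also lost without the sex term (adjusted p = 0.0677) and in 7 other settings. All mutant values of Abi3bp, Ryr1, Gpx6, Rspo1 and Egr2 lay under 5, so the order of these falls is not settled. Held at that floor, Scn4b ranked first and Abi3bp sixth among the falls, at 3.92-fold, with Ryr1 at 5.24-fold, Gpx6 at 4.33-fold and Rspo1 at 3.33-fold.

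**Figure D1:**
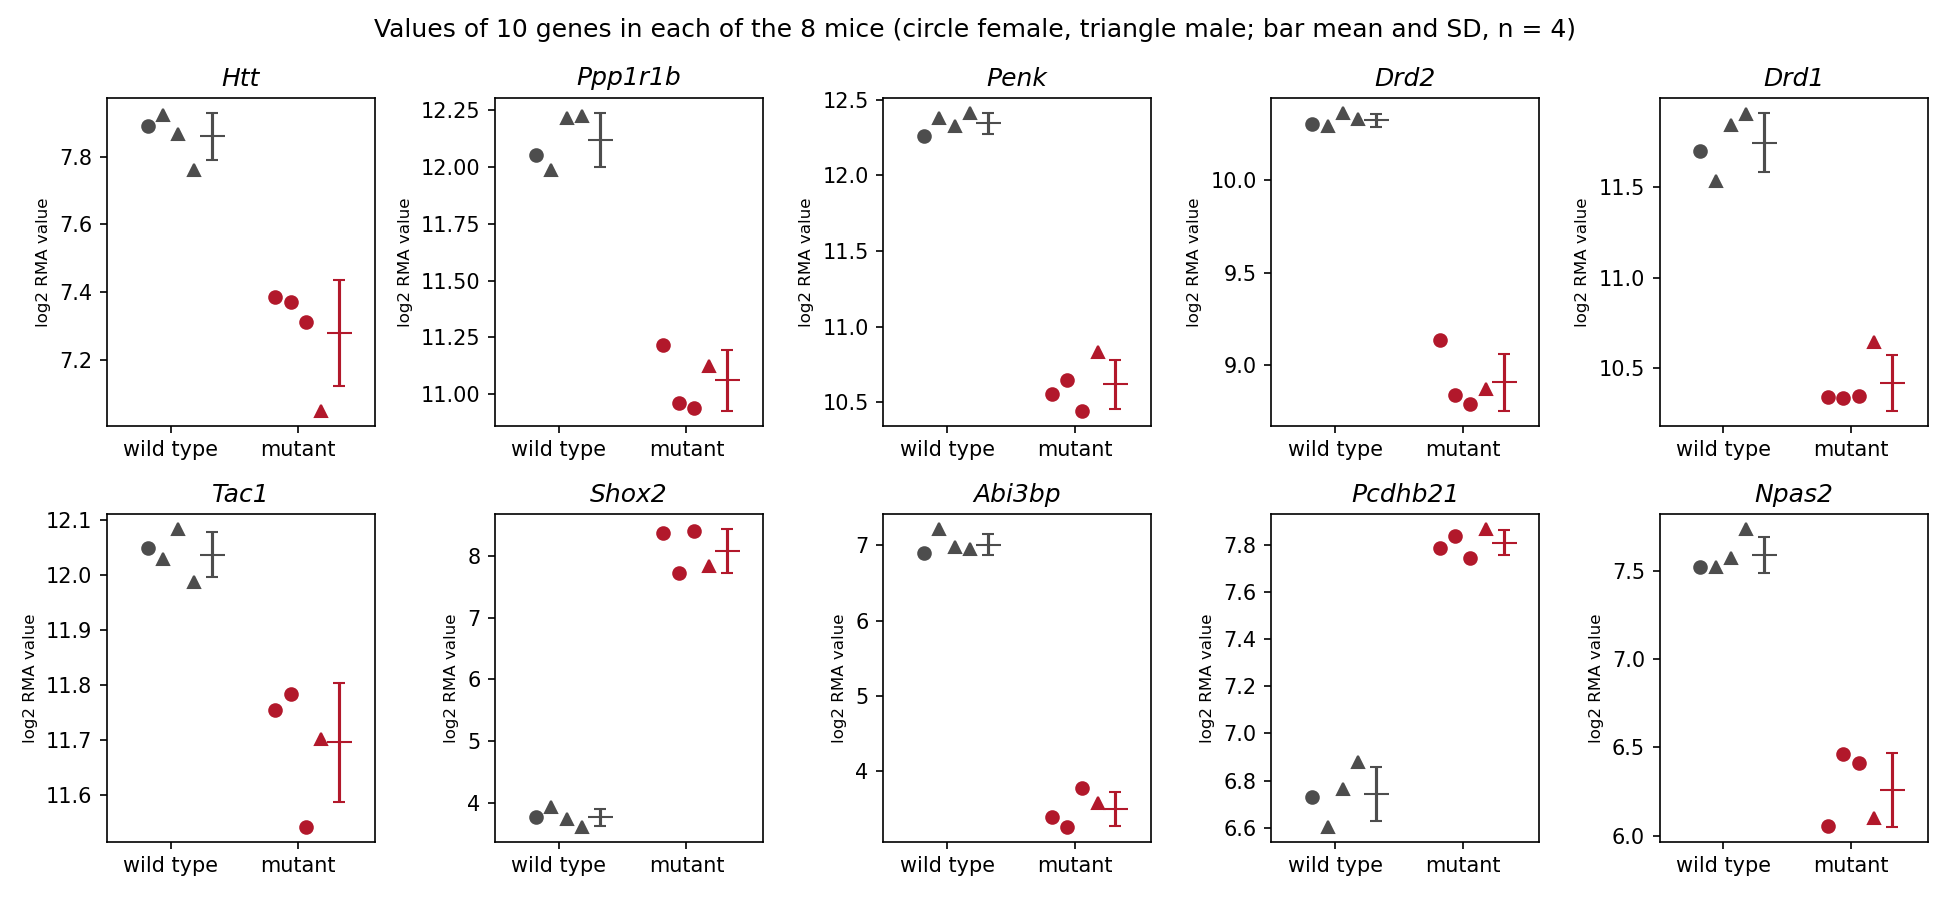
Log2 RMA values (vertical axes) of 10 genes in each of the 8 mice, with wild-type mice on the left and mutant mice on the right of each panel, circles for females, triangles for males and bars for the mean and SD of 4 mice. The 4 mutants lie apart from the 4 wild-type mice for all 10 genes, below them for Htt, Ppp1r1b, Penk, Drd2, Drd1, Tac1, Abi3bp and Npas2 and above them for Shox2 and Pcdhb21.

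Markers shared by both kinds of medium spiny neuron were lower almost throughout. Of 29 measured members of this list, 26 fell and 0 rose over all genes tested, and 29 fell adjusted over the list alone, with a median log2 change of -1.02. Besides Scn4b and Ryr1, the strongest evidence was for Rgs9, a regulator of dopamine receptor signalling that was 2.91-fold lower, and for Adcy5, the main striatal adenylyl cyclase, which was 2.74-fold lower. Ppp1r1b, which encodes the dopamine-regulated phosphoprotein DARPP-32, was 2.02-fold lower (SE of the log2 change 0.10, adjusted p = 0.000207). The list differed from other genes in the camera test with an adjusted p = 9.13e-37 at the preset correlation and an adjusted p = 0.0142 with an estimated correlation. The count was 26 without wild-type 170, 25 without wild-type 161 and 26 without mutant 191.

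Markers of the indirect pathway, the medium spiny neurons that project to the external globus pallidus, fell in 5 of 5 measured cases, and 5 of 5 adjusted over the list alone, with a median log2 change of -1.42. The orphan receptor Gpr6 was 3.71-fold lower, the enkephalin precursor Penk 3.09-fold, the dopamine receptor Drd2 2.68-fold and Plxdc1 1.49-fold. Plxdc1 had 1 of 2 probe sets in the opposite direction, not at p under 0.05. Among 10 markers of the direct pathway, the neurons that project to the substantia nigra, 4 fell and 0 rose, and 5 fell and 2 rose adjusted over the list alone. The dopamine receptor Drd1 was 2.36-fold lower, the dynorphin precursor Pdyn 2.04-fold, Slc35d3 1.55-fold and the substance P precursor Tac1 1.27-fold, and the list's median log2 change was -0.23. The indirect list gave an adjusted p = 1.02e-08 at the preset correlation and an adjusted p = 0.0142 with an estimated correlation, while the direct list gave an adjusted p = 0.0342 and lost its call with an adjusted p = 0.207 with an estimated correlation. The direct list also lost it without wild-type 161 (adjusted p = 0.0848), without dimmer genes (adjusted p = 0.0598) and on the mean of probe sets (adjusted p = 0.0558). Without wild-type 161 the indirect and direct counts were 3 and 1, and the calls of Plxdc1, Pdyn, Slc35d3 and Tac1 were lost. Without mutant 191 the counts were 3 and 3 and the calls of Plxdc1 and Tac1 were lost, and that of Tac1 was also lost without wild-type 180 and on the mean of its probe sets (adjusted p = 0.119). With sex left out of the fits without 161 or 191 the counts were 5 and 4 in both cases. Adora2a, another indirect pathway marker, was not analysed here.

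Lists of signalling, ion channel and receptor genes were lower as groups. Of 42 genes of G protein and cyclic nucleotide signalling, 20 fell and 4 rose (21 and 6 adjusted over the list alone), with Rgs4 2.56-fold lower beside Rgs9 and Adcy5. Of 45 calcium signalling genes, 22 fell and 0 rose (27 and 3 adjusted over the list alone), among them Ryr1, the scaffold gene Strn at 2.56-fold and the kinase gene Camk4 at 1.99-fold lower. Of 44 potassium and sodium channel genes, 17 fell and 1 rose (17 and 2 adjusted over the list alone), with the channel-interacting protein gene Kcnip2 2.27-fold and the background potassium channel gene Kcnk2 1.67-fold lower beside Scn4b. Of 36 genes for glutamate and GABA receptors and transport, 10 fell and 0 rose (14 and 1 adjusted over the list alone), with Grik2 2.31-fold, Gabrd 2.23-fold and Grm4 1.98-fold lower. The adjusted p at the preset correlation was 0.000136 or lower for each of these 4 lists, and the adjusted p with an estimated correlation was 0.0128, 0.0128, 0.0201 and 0.0232 in the same order. Several members, such as Rgs9, Adcy5, Ryr1 and Scn4b, are also on the medium spiny neuron list. Without mutant 191 the channel count fell to 9 and the receptor count to 5, without wild-type 161 to 11 and 5, and the rises among G protein signalling genes numbered 2 without mutant 191. With sex also left out of those fits 17 channel genes fell without either mouse, 10 receptor genes fell without 161 or 12 without 191, 3 receptor genes rose without 161, and 3 calcium signalling genes rose without either mouse.

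Of 23 neuropeptide genes, 5 fell and 0 rose (9 and 0 adjusted over the list alone), with Penk and Pdyn joined by the stress peptide gene Crh, which was 2.15-fold lower at a wild-type level of 4.16 ± 0.51 (SD, n = 4). All 8 values of Crh lay under 5, so its fold rests on signal near background, and its log2 change of -1.10 was -0.72 without wild-type 161 (adjusted p = 0.0366). The adjusted p was 3.65e-05 at the preset correlation and 0.0371 with an estimated correlation, and without wild-type 161 3 genes fell, Pdyn not among them, and 1 rose, against 5 and 1 with sex also left out. Among 16 interneuron markers, 2 fell and 0 rose (2 and 1 adjusted over the list alone), and the list had an adjusted p = 0.0793, or 0.0246 without mutant 191. The nitric oxide synthase gene Nos1 was 1.35-fold lower and the receptor kinase gene Kit 1.23-fold lower, while Kcnc1, a channel gene of fast-spiking cells, had a log2 change of 0.38 with an adjusted p = 0.0596, which passed without mutant 141 (adjusted p = 0.0161) and was 0.20 without mutant 191 (adjusted p = 0.555). Neither gene passed without wild-type 161 and Nos1 alone passed without mutant 191, and the call of Kit was lost without any of the 7 mice other than mutant 153. With sex also left out 3 genes of the list fell without either mouse. On the mean of each gene's probe sets both calls were lost (adjusted p = 0.138 for Nos1 and 0.0698 for Kit), and 1 of 4 probe sets for Nos1 and 1 of 4 for Kcnc1, the latter at p under 0.05, lay in the opposite direction.

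Immediate early and activity-induced genes included 12 that fell and 0 that rose among 28 (18 and 0 adjusted over the list alone). Homer1, a postsynaptic scaffold gene, was 1.83-fold lower, Egr3 1.82-fold and Per1 2.04-fold, while Bdnf, with all 8 values under 5, had a log2 change of -0.36 (adjusted p = 0.0982) and passed without mutant 141 (adjusted p = 0.0325). The list's score in wild-type 161 was 0.93, against -0.21 to 0.20 in the other 3 wild-type mice and -0.35 to -0.09 in the mutants. Without wild-type 161 the count was 4, and with sex left out of the fit it was 5 without 161, 5 without mutant 191 and 4 without wild-type 170. The list had an adjusted p = 2.48e-10 at the preset correlation and lost its call with an adjusted p = 0.197 with an estimated correlation.

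Genes of the circadian clock were lower in 10 of 18 cases, and none was higher (10 and 0 adjusted over the list alone). Npas2, a clock transcription factor expressed in forebrain, was 2.56-fold lower, the output factor Hlf 1.87-fold and the negative regulator Per2 1.79-fold. The adjusted p was 2.04e-07 at the preset correlation and 0.0601 with an estimated correlation, so this call was lost. The count was 5 without mutant 191 and 10 when sex was left out of that fit, and the time of day of tissue collection is not given in the sources used here.

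Clustered protocadherin beta genes, neighbouring genes for cell surface adhesion molecules, rose in 11 of 22 cases and fell in 0 (12 and 0 adjusted over the list alone), with a median log2 change of 0.35. Pcdhb21 rose 2.13-fold, Pcdhb3 1.94-fold and Pcdhb16, with 1 of 3 probe sets in the opposite direction, 1.82-fold, and the list gave an adjusted p = 3.73e-08 at the preset correlation and 0.0142 with an estimated correlation. The count was 6 without wild-type 161 and 4 without mutant 191, against 10 and 9 with sex left out of those fits. These genes are close in sequence, and signal shared between their probe sets was not analysed here.

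Of 51 developmental transcription factors chosen as low in adult striatum, 6 rose and 0 fell (6 and 0 adjusted over the list alone), led by Wt1 at 2.55-fold, Hoxc4 at 1.84-fold and Onecut1 at 1.83-fold, all at wild-type levels of 3.86 to 4.55. The list as a whole did not differ from other genes (adjusted p = 0.287), with a median log2 change of -0.03 and a mean of 0.08. The count was 3 without wild-type 161, where the call of Onecut1 was lost, and 4 without mutant 191, against 4 and 8 with sex left out of those fits, and the list passed without mutant 191 (adjusted p = 0.0405). The calls of Wt1, Hoxc4 and Onecut1 were lost when values were floored at log2 of 32, with an adjusted p of 0.122, 0.127 and 0.161.

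Proteasome subunit genes were higher in 9 of 34 cases and lower in 0 (16 and 0 adjusted over the list alone), and 33 of the 34 had a log2 change above 0. The immunoproteasome subunit gene Psmb10 rose 1.65-fold, Psmd1 1.31-fold and Psma1 1.30-fold, and the adjusted p was 1.09e-08 at the preset correlation and 0.0331 with an estimated correlation. Of 4 probe sets for Psma1, 2 lay in the opposite direction, and its call was lost on the mean of probe sets (log2 change 0.14, adjusted p = 0.291). The calls of Psmd1 and Psma1 were lost without either of mice 161 and 191. The count was 1 without wild-type 161 and 1 without mutant 191, against 8 and 11 with sex left out of those fits. Interferon response genes rose in 6 of 26 cases and fell in 0 (8 and 1 adjusted over the list alone), among them the class I histocompatibility genes H2-D1 at 2.10-fold and H2-K1 at 1.76-fold and Xaf1 at 1.29-fold. H2-D1 had 9 probe sets, of which 1 lay in the opposite direction at p under 0.05, and so did 1 of 4 for H2-K1 and 1 of 2 for Xaf1 without reaching that p. The strain was a hybrid, and sequence differences between the mice under the probe sets of H2-D1 and H2-K1 were not analysed here. On the mean of probe sets the calls of H2-D1 (log2 change 0.25, adjusted p = 0.0571) and Xaf1 (log2 change 0.14, adjusted p = 0.316) were lost, and that of Xaf1 was lost without mouse 161 or 191. This list passed at the preset correlation (adjusted p = 0.000996) and lost its call with an adjusted p = 0.197 with an estimated correlation, and its count was 2 without either of mice 161 and 191, 5 and 4 with sex left out, and 4 without wild-type 170, where 1 gene fell.

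Respiratory chain genes had a median log2 change of 0.10 over 54 members, of which 2 rose and 0 fell over all genes and 0 passed adjusted over the list alone. Among all genes tested a larger share, 6.40%, rose. Atp5g1 rose 1.35-fold and Cyc1 1.24-fold, Sdha had a log2 change of 0.27 (adjusted p = 0.061), and Ppargc1a, the coactivator of mitochondrial biogenesis, one of 0.27 (adjusted p = 0.0874) that was 0.16 without wild-type 161 (adjusted p = 0.574). The list's call at the preset correlation (adjusted p = 0.00137) was lost with an adjusted p = 0.102 with an estimated correlation, and neither gene passed without mouse 161 or 191, where 0 genes of the list passed, against 2 and 3 with sex left out. The call of Cyc1 was lost in 5 of the 8 fits that left a mouse out. Of 2 probe sets for Atp5g1 and 4 for Sdha, 1 each lay in the opposite direction, and the call of Atp5g1 was lost on the mean (adjusted p = 0.179).

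Of 32 heat shock and chaperone genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Fkbp4 1.41-fold and Ahsa1 1.37-fold higher and Chordc1 1.44-fold lower. Of 19 p53 targets, 1 rose and 2 fell (1 and 2 adjusted over the list alone), Polk being 1.30-fold higher, Plk2 1.78-fold lower and Cdkn1a 1.49-fold lower. Of 20 cholesterol synthesis genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone), Lss being 1.37-fold higher, Insig1 lower by a log2 change of -0.59 and Msmo1 1.47-fold lower. Of 18 glucocorticoid-responsive genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone), namely Per1, Cdkn1a and Klf9, which was 1.27-fold lower. The adjusted p of these 4 lists was 0.156, 0.287, 0.181 and 0.0648 at the preset correlation. Among all genes tested 12.4% passed, so counts this small can arise in any list of this size. Single mice turned 3 of these into calls: the heat shock list passed without wild-type 161 (adjusted p = 0.000325), the cholesterol list without mutant 191 (adjusted p = 0.0344), and the glucocorticoid list without mutant 154 (adjusted p = 0.00793), wild-type 161 (adjusted p = 0.000681) or wild-type 170 (adjusted p = 0.0366). The mean log2 change of the glucocorticoid list moved from -0.15 to -0.33 without 161 and to 0.035 without 191, and that of the heat shock list from 0.07 to 0.20 and -0.06. Without wild-type 161, 2 heat shock genes rose and 0 fell, 2 p53 targets fell and 0 rose, 0 cholesterol genes passed and 3 glucocorticoid-responsive genes fell. Without mutant 191, 0 heat shock genes rose and 2 fell, 1 cholesterol gene rose and 1 fell, and 1 p53 target and 1 glucocorticoid-responsive gene fell. With sex also left out, 8 heat shock genes rose without 161 and 6 without 191, 1 falling in each case. In those fits 1 p53 target rose and 3 fell and 1 cholesterol gene fell, and glucocorticoid-responsive genes gave 4 falls without 161 and 3 falls and 1 rise without 191. Among single genes, Lss lost its call in 6 of the 8 fits that left a mouse out and Insig1 in 4, Klf9 in 5 and Polk in 3. The log2 change of Lss, 0.46, was 0.17 without 161 (adjusted p = 0.558) and 0.74 without 191, and that of Chordc1, -0.53, was -0.22 without 161 (adjusted p = 0.42) and -0.84 without 191. Without 191 Cdkn1a moved from -0.57 to -0.36 (adjusted p = 0.348) and Klf9 from -0.34 to -0.21 (adjusted p = 0.391), and the calls of Fkbp4 and Ahsa1 were lost, while those of Fkbp4 and Msmo1 were lost without 161. On the mean of probe sets the calls of Lss (adjusted p = 0.322), Polk (adjusted p = 0.103) and Klf9 (adjusted p = 0.634) were lost, and 1 of 2 probe sets for Plk2 and 3 of 7 for Klf9 lay in the opposite direction.

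Glial markers passed the test in both directions, where 12.4% of all genes tested passed. Gfap, the intermediate filament gene of astrocytes, rose 1.39-fold from 8.74 ± 0.37 to 9.48 ± 0.23 (SD, n = 4 each, adjusted p = 0.0341) with overlapping groups, a fold that is adjusted for sex, and S100b rose 1.34-fold while the bicarbonate transporter gene Slc4a4 was 1.37-fold lower, so that 2 of 23 astrocyte markers rose and 1 fell (3 and 5 adjusted over the list alone). Of 17 reactive astrocyte genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone), with Vim 1.51-fold higher and S100a10 1.87-fold lower. None of 26 microglial markers passed in either direction (0 adjusted over the list alone), and Aif1 had a log2 change of -0.36 (adjusted p = 0.0509), which passed without wild-type 180 (adjusted p = 0.0167). Of 26 oligodendrocyte markers, 4 rose and 3 fell (5 and 5 adjusted over the list alone), with Evi2a 1.42-fold and Olig1 1.35-fold higher and Car2 1.56-fold lower, while Mbp had a log2 change of -0.13 (adjusted p = 0.415), or -0.070 without mutant 191. This list's median was 0.04 and its mean -0.0043. Of 13 markers of oligodendrocyte precursors, Olig1 and Lhfpl3, 1.31-fold higher, rose and 0 fell (3 and 0 adjusted over the list alone), while Bmp4, with all 8 values under 5, had a log2 change of 0.30 (adjusted p = 0.0679). The adjusted p of these 5 lists at the preset correlation was 0.214, 0.577, 0.937, 0.937 and 0.0968, and the astrocyte list passed without mutant 191 (adjusted p = 0.0438) and the precursor list without wild-type 161 (adjusted p = 0.0405). Without wild-type 161 or mutant 191, at most 2 genes of any of these lists passed, where the calls of S100b, Gfap, Vim, Evi2a, Olig1 and Lhfpl3 were lost without either mouse. With sex also left out, 4 reactive astrocyte genes rose and 1 fell without 161, and 3 rose and 1 fell without 191. Oligodendrocyte markers then gave 3 rises and 4 falls without 161 and 3 and 5 without 191, astrocyte markers 2 and 2 and 2 and 3, precursor markers 1 and 0 in both and microglial markers 0. Without wild-type 170, 2 reactive astrocyte genes rose and 3 astrocyte markers fell. The call of Slc4a4 was lost without 191 and that of Car2 without 161. The call of Gfap was also lost without mutant 153 (adjusted p = 0.0545) and without wild-type 200 (adjusted p = 0.0696). Of 2 probe sets for Evi2a and 5 for Slc4a4, 1 each lay in the opposite direction, and the call of Evi2a was lost on the mean (adjusted p = 0.173).

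Markers of other cells that a dissection can carry along were also examined. Of 27 endothelial and mural markers 1 fell, Cdh5 at 1.36-fold with all 8 values under 5 (1 adjusted over the list alone), while Abcb1a and Cldn5 had log2 changes of -0.49 (adjusted p = 0.0511) and -0.51 (adjusted p = 0.0821). Abcb1a passed without wild-type 180 (adjusted p = 0.0359) or 200 (adjusted p = 0.0337), and Cldn5 stood at -0.96 without mutant 191 (adjusted p = 0.00966) and at -0.06 without wild-type 161 (adjusted p = 0.89). The list's call at the preset correlation (adjusted p = 0.000996) was lost with an adjusted p = 0.249 with an estimated correlation. Of 18 cortical neuron markers 2 fell, Nptx1 at 2.88-fold and Fezf2 at 1.59-fold (4 adjusted over the list alone), and Dkk3 had a log2 change of -0.30 (adjusted p = 0.0569), which passed without mutant 153 (adjusted p = 0.0488) and was -0.18 without mutant 191. The cortical list's call at the preset correlation (adjusted p = 0.00102) was also lost, with an adjusted p = 0.249 with an estimated correlation, and without a sex term (adjusted p = 0.0876). The cortical score ranged from -0.53 in mutant 191 to 0.40 in mutant 154, against -0.10 to 0.34 in wild-type mice, and the calls of Nptx1 and Fezf2 were lost without a sex term and without mutant 191. Those of Nptx1, Cdh5 and Ccdc153 were lost without wild-type 161, where the log2 change of Ccdc153 went from -0.76 to -0.40, and that of Cdh5 without mutant 191. With sex also left out, 1 cortical marker fell without 161, and 1 rose and 1 fell without 191. Of 19 choroid plexus and ependyma markers, Spag6 was called higher, at 4.53 ± 0.44 against 3.18 ± 0.19 (SD, n = 4 each), with all 8 values under 5 and so near background, and Ccdc153 was 1.69-fold lower (1 and 1 adjusted over the list alone), Rarres2 had a log2 change of -0.39 (adjusted p = 0.0847, or 0.0402 without mutant 153), the list had an adjusted p = 0.0848 and passed without mutant 141 (adjusted p = 0.000449), mutant 191 (adjusted p = 0.00249) or wild-type 170 (adjusted p = 0.0334), and its score ranged from -0.60 to 0.93 within the mutant group. No marker passed among 18 for thalamic, hypothalamic and other non-striatal neurons (adjusted p = 0.366) or among 9 for blood (adjusted p = 0.78), with 0 in each adjusted over the list alone, though 1 non-striatal marker rose without wild-type 170 and 1 fell with sex left out without 161 or 191. The blood list had a median log2 change of 0.0009 and a mean of -0.02.

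**Figure D2:**
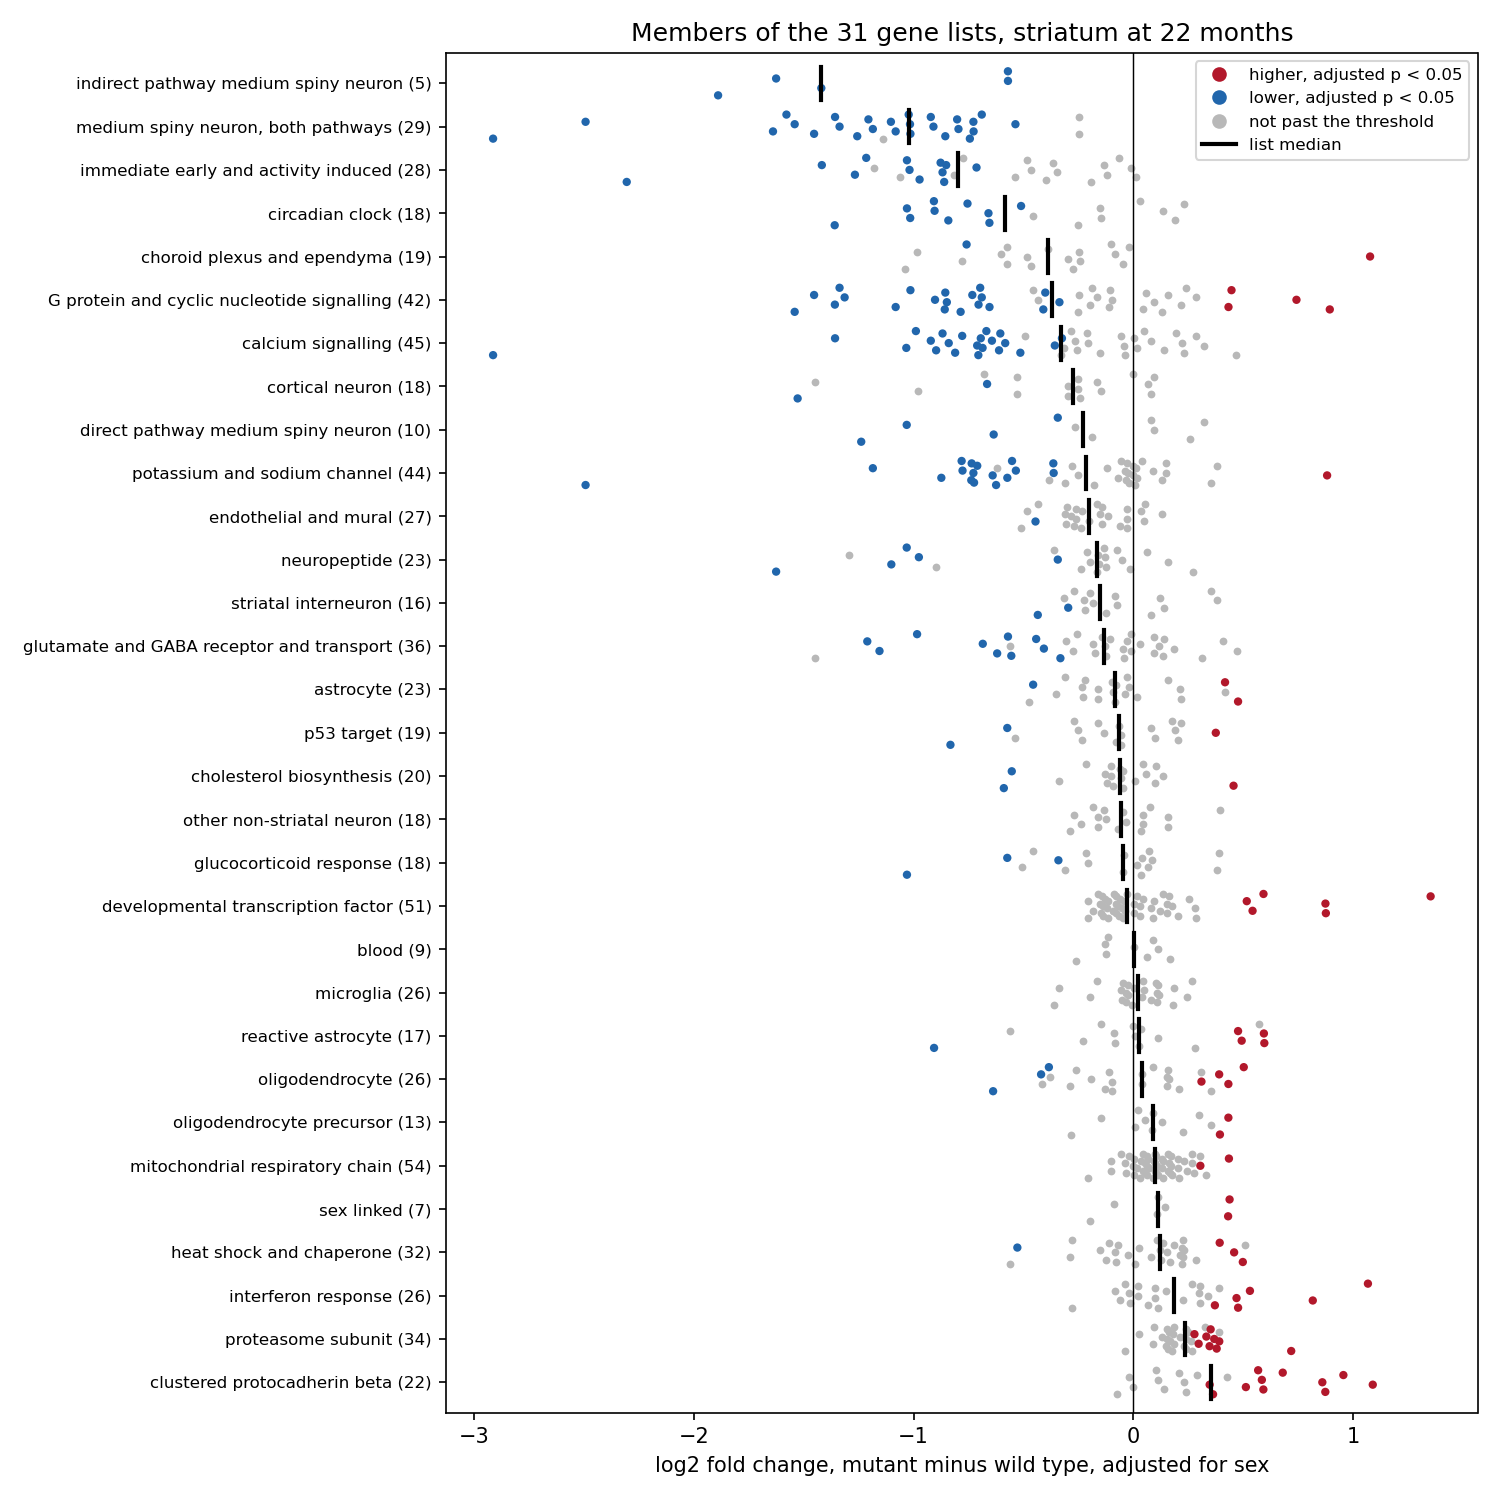
Log2 fold changes of mutant minus wild-type mice, adjusted for sex (horizontal axis), for each measured member of the 31 gene lists (vertical axis, number of members in parentheses), in red for members that rose, blue for those that fell, grey for those that did not pass, and a black bar for the list's median. The medians run from -1.42 for indirect pathway markers to 0.35 for the protocadherin beta genes.

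With the mice as the unit, the score of 16 of the 31 lists separated the groups completely. This gives the smallest p an exact permutation test can reach here, 0.0286. After adjustment over the lists 0 passed, and the lowest adjusted permutation p was 0.0554. With that smallest p a list could pass the adjustment only if more than 16 lists had reached it. No list could pass on its own, however far apart its groups lay, so this result decides nothing about single lists. The medium spiny neuron score was -0.59 ± 0.09 (SD, n = 4) in mutant and 0.59 ± 0.07 in wild-type mice. Scores and their permutation tests were not adjusted for sex. Adjustment moved the difference between the groups from -1.18 to -1.12 for this list and from -0.22 to -0.43 for cortical neurons. For immediate early genes it moved from -0.48 to -0.73, and for sex-linked genes from -0.02 to 0.14. In the camera test, 16 of the 31 lists passed at the preset correlation and 9 with an estimated correlation. In fry, which asks whether the genes of a list move on balance one way, the interneuron (adjusted p = 0.0343), p53 target (adjusted p = 0.0134) and oligodendrocyte precursor lists (adjusted p = 0.0132) also passed, and the endothelial and the cortical list did not (adjusted p = 0.0988 for both).

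**Figure D3:**
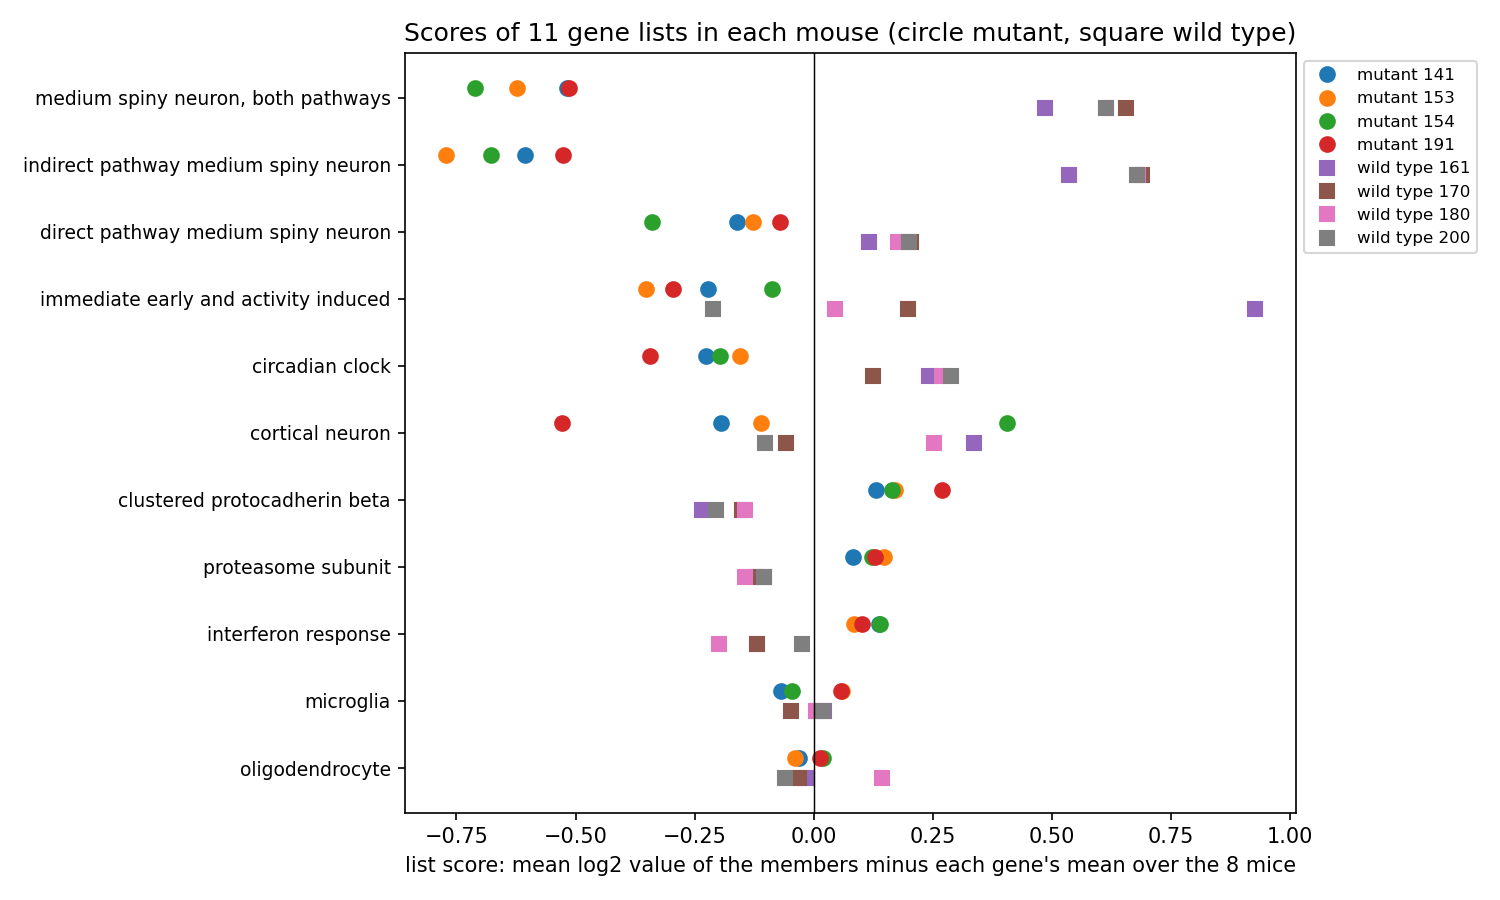
Scores of 11 gene lists (vertical axis) in each mouse, as the mean log2 value of the members minus each gene's mean over the 8 mice (horizontal axis), with circles for mutants, squares for wild-type mice and 1 colour per mouse. Medium spiny neuron scores lie between -0.71 and -0.51 in mutants and between 0.49 and 0.65 in wild-type mice, while microglia scores overlap.

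Measures of RNA quality stood apart in 1 mouse. In wild-type 170 the 3' probe set for Gapdh exceeded the 5' probe set by 1.37 on the log2 scale, against 0.32 to 0.43 in the other 7 mice, and that for beta-actin by 2.65, against 1.23 to 1.51. Its 18S ribosomal RNA probe set read 10.0, against 7.16 to 8.43 in the others. The groups did not differ in the Gapdh measure (exact permutation p = 0.8286) or the beta-actin measure (exact permutation p = 0.486). Without this mouse 2152 genes differed between the genotypes. Hybridisation controls, which do not measure RNA quality, also varied between arrays. BioB ran from 4.84 in mutant 191 to 9.40 in mutant 153, and Cre from 10.4 to 13.7 in the same mice. Mutant 191 was thus the lowest in both, and whether this bears on its other values was not tested.

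Female and male mice differed in 5 genes, a comparison that also checks the recorded sexes. Xist, the RNA that silences an X chromosome in females, was at 11.33 ± 0.18 (SD, n = 4) in females and 6.43 ± 0.58 in males, and 8030474K03Rik was also higher in females, by 3.32 on the log2 scale (adjusted p = 1.4e-06). The Y-linked genes Eif2s3y, Kdm5d and Uty were lower in females, with log2 changes of -4.57, -2.37 and -1.41 (adjusted p = 5.06e-09, 1.98e-05 and 0.045). Female values of these 3 genes and male values of 8030474K03Rik all lay under 5, so the exact sizes rest on signal near background. All 8 mice matched their recorded sex in Xist and Eif2s3y. Ddx3y was not analysed here. Between the genotypes Xist had a log2 change of 0.11 (adjusted p = 0.861) and Kdm5d one of -0.20 (adjusted p = 0.404), or -0.13 without mutant 154, while 2 of 7 sex-linked genes rose in the mutants, the X-linked Eif2s3x and Kdm5c, each 1.35-fold (2 and 0 adjusted over the list alone; list adjusted p = 0.214, or 0.0372 without wild-type 161). Of 9 probe sets for Kdm5c, 3 lay in the opposite direction, 1 of them at p under 0.05, and neither gene passed without mouse 161 or 191 or on the mean of probe sets (adjusted p = 0.655 for Kdm5c and 0.0512 for Eif2s3x).

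An interaction of genotype and sex passed the threshold for 1 gene, Npas4, an activity-induced transcription factor named here after its value was seen, at -3.11 on the log2 scale (SE 0.26, adjusted p = 0.00985). It stood at 7.31 in wild-type 161, the single female wild-type mouse, at 5.25 to 5.57 in the male wild-type mice, at 4.46 to 4.90 in the female mutants and at 5.91 in the male mutant. The female wild-type and the male mutant arm each hold 1 mouse, and wild-type 161 also had the highest score of the immediate early list, so this value cannot be separated from that of single mice. An interaction p under 0.05 before adjustment was found for 917 genes, or 5.04%, where chance gives about 910.

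Genes close to Htt on its chromosome passed about as often as others. Among the 50 nearest tested genes on each side, 13 of 100 differed between the genotypes, or 13%, against 2228 of 17928 placed genes elsewhere, or 12.4% (odds ratio 1.05, 95% interval 0.54 to 1.90, Fisher's exact p = 0.879).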

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

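The comparisons of single mice in the cortical score, of direct pathway with shared markers and of each marker with the median were chosen after the results were seen, as was the requirement below that the interval of a share clear its bound. The first pattern is the number of genes that differed between the genotypes, 2258. Chance as its source is argued against, but not excluded, by other splits of the mice into groups of 4. Of the 34 splits that could be fitted with sex, 1, the real one, gave as many genes. The highest of the other splits gave 0. A share of 1 in 34 is the smallest this test can give. The other splits also mix the genotypes, so the genotype difference adds to their spread and leaves few calls possible. The split by sex could not be fitted with a sex term and gave 5 genes without it. The imbalance of the sexes as the source of most calls is argued against by the count for sex itself, which was 0.221% of that for genotype. Before adjustment, however, 1932 genes had a limma p under 0.05 for sex, where chance gives about 910, against 4703 for genotype. Without the sex term 2758 genes passed and 86.0% of the main calls were kept, so an effect of sex on single calls stays open. The degraded RNA of wild-type 170 is argued against by the 2152 genes found without that mouse, above the median of 1820 in the other 7 fits that left a mouse out. Any difference in breeding, housing or tissue collection that followed genotype also stays open and was not tested.

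The second pattern is the fall of medium spiny neuron markers. Cortical or other tissue in the mutant dissections, as the source of the whole fall, is argued against by the scores of mutant minus wild-type mice. They were -0.22 for cortical and -0.03 for other non-striatal neurons (exact permutation p = 0.429 for each). Adjusted for sex these differences were -0.43 and -0.04. In the unadjusted cortical and non-striatal scores the highest mutant exceeded the highest wild-type mouse by 0.07 and 0.01, against a medium spiny neuron fall of 1.18. Mutant 154 had the highest cortical (0.40) and non-striatal score (0.07) and the lowest medium spiny neuron score (-0.71), so some carried tissue there stays open. The other mutants had cortical scores of -0.53 to -0.11 and medium spiny neuron scores of -0.62 to -0.51. An equal fall of all markers, which a lower share of these neurons would give for genes that no other cell makes and whose probe sets respond alike, is argued against by 16 of 28 bright markers whose 95% interval excludes the median of -1.02, 8 below and 8 above it, where chance gives about 1.4; they run from Scn4b at -2.49 (95% interval -2.68 to -2.30) to Meis2 at -0.25 (-0.44 to -0.06). The direct pathway score fell less than that of the shared markers by 0.83 (exact permutation p = 0.0286). Its members went both ways, 6 with a log2 change below 0 and 4 above, so this score decides little about an equal fall. A lower share in which other cells make part of each transcript, or probe sets compress falls unequally, cannot be told apart from lower expression within the neurons, because neither was measured, and the 28.6% of markers above the median passed the bound of 25% set before by less than its spread (exact binomial interval 13.2% to 48.7%).

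The third pattern is the genes around Htt. DNA from the embryonic stem cell strain may flank the altered gene, but an excess of changed genes among the 100 nearest was not seen, with an odds ratio of 1.05 whose upper 95% bound of 1.90 lies under the bound of 2 set before. With 20 genes on each side the odds ratio was 0.782 and its upper bound 2.19, so a smaller effect or one of a few flanking genes stays open.

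Of 272 groups of 4 values examined, 27 had a mouse whose gap to the nearest other value took up most of the group's range, where chance gives about 1 in 20, or 13.6. Wild-type 170 stood apart in the 3' to 5' measures of Gapdh (0.984 of the range) and beta-actin (0.949), in 18S ribosomal RNA (0.842), with low scores for calcium signalling (0.846) and for potassium and sodium channels (0.953) and with a high blood score (0.874). Wild-type 161 stood apart with low values of Plxdc1 (0.951) and Kdm5d (0.864), a low indirect pathway score (0.924) and a high heat shock score (0.862). Mutant 191 stood apart with low Skor1 (0.953), high Drd1 (0.956), low Xist (0.925) and a high sex-linked score (0.853). As the single female wild-type and the single male mutant, mice 161 and 191 stand apart in Kdm5d and Xist by sex. Mutant 153 had low Plxdc1 (0.906) and high Homer1 (0.8294), Polk (0.856) and Onecut1 (0.853). Mutant 154 had low Pdyn (0.876), Gabrd (0.960) and Car2 (0.837). Mutant 141 had high Aif1 (0.844), and wild-type 180 had low Aif1 (0.871) and Kcnip2 (0.901). Wild-type 200 had high Rgs9 (0.863), low Pcdhb3 (0.843) and a low oligodendrocyte precursor score (0.852). The interaction of genotype and sex for Npas4 was -3.11 on the log2 scale, but wild-type 161, whose immediate early score of 0.93 was the highest, and mutant 191 are each the single mouse of their sex in their group, so a difference between the sexes cannot be separated from single mice.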

How the results depend on the processing

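The fits without sex and without named mice were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Under settings other than single mice left out, 64 counts stayed within 1.5 times and 9 did not, and 2 odds ratios changed side. The exceptions included 1325 genes changed, 688 higher and 637 lower without moderation, where each gene's spread is estimated from its own values alone. Further exceptions were 1029 genes at an adjusted p under 0.01 and 1403 genes at least 1.5-fold on every probe set, where more units are tested. So were 727 genes higher without sex and without mice 161 and 170, where fewer mice enter, and 9 lists with an estimated correlation. Genes changed between the sexes numbered 1 after the dimmer genes were removed and 14 over every probe set. The odds ratio near Htt was below 1 with 20 genes on each side, at 0.782, and with 100, at 0.825, and the cause was not tested. Leaving out each mouse gave 702 to 2258 genes changed, 292 to 1145 higher, 410 to 1113 lower, 600 to 779 at least 1.5-fold, 4 to 6 between the sexes and 16 to 21 lists. The low values came from mutant 191 (702) and wild-type 161 (864), whose loss leaves a group of a single sex. With sex in the fit, the comparison without 191 sets the female mutants against 161 alone. The comparison without 161 sets 191 alone against the male wild-type mice, so each of these fits rests on a single mouse on 1 side. Of the 2258 calls, all kept their direction in each of these 8 fits and 28.7% to 90.4% kept their call. These genes were chosen by their p in the same data, and each fit shares all but 1 mouse with the main fit. A change of direction was thus unlikely beforehand, and its absence tests little. The sign of the value or the direction of the list test changed in uncalled results: Xist (-0.12 on the mean of probe sets, -0.080 to 0.30 without single mice), Mbp (0.013 without sex and 191), the list means of microglia (0.000189 without sex, -0.0066 without dimmer genes, 0.0017 on the mean of probe sets, -0.041 to 0.064 without single mice), oligodendrocytes (-0.019 without sex, -0.0061 without dimmer genes, 0.0058 on the mean of probe sets, -0.023 to 0.026), glucocorticoid response (-0.33 to 0.035), sex-linked genes (-0.024 without sex), other non-striatal neurons (8.3e-05 without dimmer genes), reactive astrocytes (-0.10 without dimmer genes), heat shock (-0.055 to 0.20), choroid plexus (-0.73 to 0.00082) and blood (-0.11 to 0.064), and without single mice the scores of microglia (-0.019 to 0.023), oligodendrocytes (-0.043 to 0.026), choroid plexus (-0.49 to 0.036), blood (-0.047 to 0.047) and sex-linked genes (-0.13 to 0.035, and 0.14 when adjusted for sex). The blood list gave no value without dimmer genes, nor did Bdnf, Bmp4, Cdh5, Crh and Spag6 at the floor, under which all their values lie. Signal near background limits the folds of the dimmest genes, and 19 of 89 named calls were not kept at that floor, 3 of them of genes with no value there.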

Other observations

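All tests in this part were chosen after values of the same genes had been seen. Gene families defined by the letters of the symbol before the first digit gave a grouping apart from the fixed lists, though the Pcdhb, Rgs and Pde families share members with them. Of 126 families with at least 15 tested genes, 6 departed from the other genes after adjustment over 252 Fisher's exact tests. A prefix is not a function, and such a family can hold genes for interacting proteins, such as Pde4dip and Rgs7bp. Besides the protocadherin beta genes, genes with the Polr prefix were higher more often than other genes, 7 of 25 (28.0%) against 6.37% (adjusted p = 0.0376). They included Polr2a, the large catalytic subunit of RNA polymerase II, at a log2 change of 0.85 (SE 0.14), and Polr3a of RNA polymerase III at 0.50 (SE 0.11). Genes with the Cdh prefix, most of them cadherins, were lower more often, 7 of 21 (33.3%) against 5.98% (adjusted p = 0.00968), led by Cdh4 at -1.31 (SE 0.11) and including Cdh13 at -0.67 and Cdh8 at -0.52. The 7 also include Cdh5, all of whose values lay under 5 and so near background. Genes with the Rgs prefix, Rgs7bp among them, fell in 9 of 21 cases and rose in 1, Rgs19, at a log2 change of 1.19 (SE 0.08). Genes with the Pde prefix, Pde4dip among them, fell in 8 of 25 cases and rose in 1, Pde4d, at 0.74. Zinc finger genes with the Zfp prefix were lower less often than other genes, 7 of 336 (2.08%) against 6.09% (adjusted p = 0.0434), while 35 were higher (10.4% against 6.32%, adjusted p = 0.117), led by Zfp647 at 1.09 (SE 0.10). After quantile normalization again or median centring, the counts of the 5 families other than Zfp moved by at most 1 gene, with Polr genes higher in 6 and 7 of 25 cases, and Zfp genes were higher in 32 and 38 cases and lower in 7. When each mouse was left out in turn, the Pcdhb and Rgs families passed in 8 of 8 fits, Pde in 7 (adjusted p = 0.186 without mutant 191), Cdh in 6, with 2 genes lower without mutant 191 and 1 without wild-type 161, Zfp in 4 and Polr in 1, without mutant 153, so the Polr result rests on no stable call. Genes of a family can share regulation and probe sequence, so they are not independent and these p-values are too small by an unknown amount. That such families hold more changed genes is thus a hypothesis from the same data, which 5 of the 6 families are in line with over all mice, since Zfp genes passed for holding fewer falls, and the number with an excess ran from 2 to 6 when a mouse was left out.

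The 50 genes that rose at least 2-fold had a median log2 value of 5.71 in wild-type and 6.96 in mutant mice, and 31 of them (62.0%) lay below 6.19, the median of all genes, in wild-type mice. The 120 genes that fell at least 2-fold had a median of 8.25 in wild-type and 6.89 in mutant mice, and 41 of them (34.2%) ended below 6.19. The starting median of the risers minus the final median of the fallers was -1.18. These genes were chosen by their change, so the levels describe them and test no explanation.

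A further hypothesis is that indirect pathway markers lie further below wild type than direct pathway markers. The indirect minus direct score was -0.47 ± 0.13 (SD, n = 4) in mutant and 0.47 ± 0.04 in wild-type mice, a difference of -0.94 (exact permutation p = 0.0286, the smallest possible). With members at a mean log2 value of 8 or more, 3 indirect and 4 direct markers, the difference was -1.06 (exact permutation p = 0.0286). Penk fell further than Tac1, with a difference of -1.38 between the groups (exact permutation p = 0.0286), but Drd2 and Drd1 did not differ in this way (-0.08, exact permutation p = 0.571). Pdyn, another direct pathway peptide gene, was 2.04-fold lower, between Tac1 at 1.27-fold and Penk at 3.09-fold, and its difference from Penk was not tested. The receptors thus do not show the difference between the lists, which rests on 5 and 10 markers. Of the 10 direct markers 4 had a log2 change above 0, against 0 of the 5 indirect ones. Direct markers that did not fall are therefore part of the difference.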
